A study of Tachycineta bicolor with 20 samples.

How the data were processed

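Ovaries of 20 adult female tree swallows, each from a separate bird, were profiled by RNA sequencing. Per the labels' protocols, tissue was frozen in the field on dry ice, RNA was extracted with Trizol, and libraries were made with a kit that keeps strand and selects mRNA. Per the submitters' processing notes, CASAVA, fastp 0.20.1, Bowtie2 2.4.2 and SAMtools were used. The role of each tool, the reference the reads were matched to, the counting program and its strand setting are not given in the sources used here. The authors deposited a table of whole-number read counts per transcript and bird, with no normalization, which was the starting point here.

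The table held 14782 transcripts from 13412 ID stems, of which 1132 had more than 1 transcript. How reads shared between transcripts of a stem were assigned is not given in the sources used here, so counts of such transcripts are uncertain. One further line, which names no transcript, had a count of 0 in each library and was left out. Each of the 20 columns was matched to its bird by title. The IDs are not paired with gene names in the files, and 0 of them matched any of the 852 symbols in the 32 gene lists fixed beforehand (steroid synthesis, ovarian cell types, other organs, stress and immune pathways and others). Therefore none of the list tests was run, counts were not summed per symbol, and transcripts are named by ID only.

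Birds were grouped by treatment and day from the labels. Bird numbers follow sample order and pair no birds across groups. Transcripts were kept with filterByExpr at a minimum count of 10 and a minimum total of 15, which left 13742. The 1040 filtered transcripts held at most 0.0856% of the counts of any library. Counts were scaled with TMM factors and fitted in edgeR 4.0.16 (R 4.3.3) by the robust quasi-likelihood method, with 4 group means and no covariate. The contrasts tested were treatment on each day, treatment averaged over the days, the treatment by day interaction, and the difference between days within each treatment. A transcript was called at a Benjamini-Hochberg adjusted p under 0.05. The common biological coefficient of variation was 0.319. Standard errors of log2 fold changes are Wald errors from the same fit. Group values are CPM (counts scaled to the library total times its TMM factor) with the SD over birds. Values tested one at a time used two-sided permutation tests, exact where arrangements could be enumerated.

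Fewer than 10 IDs passed in every contrast, so up to 2 higher and 2 lower transcripts of smallest p were named, as the rule set beforehand for IDs without a symbol allows. This was done for 3 contrasts only (treatment on each day and days within controls), a restriction chosen after the results were seen.

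The 41 pairs of birds within groups differed by a chi-square per degree of freedom of 12.6 to 89.1 over transcripts, far above sampling noise, so no library was counted as a duplicate. The test was checked on counts simulated independently for each transcript, where 0 to 14 false calls were made per run, in runs of 98 to 205 calls. Such counts lack the variation that transcripts of the real birds share, so the check cannot show how the test behaves under it. Recovery was also measured on the real counts. In each of 5 repeats, 200 transcripts were given a 2-, 4- or 8-fold change by random thinning, and the share called was recorded. Those changed transcripts also loosen the adjusted threshold, since 8.6 to 82 unaltered transcripts per comparison were then called where the real counts gave 0 or 1. The shares recovered are therefore higher than the sensitivity behind the real counts of calls.

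The groups, contrasts, main test, filter, thresholds and the following alternatives were set before the data were examined. These were RLE factors, no filter, a stricter filter of 1 CPM in 10 libraries, DESeq2 1.42.0, limma 3.58.1 voom with sample weights, only the compared groups in the fit, surrogate variables from sva 3.50.0, an adjusted p under 0.10, and each bird left out in turn. Components of the 500 transcripts of highest variance (log2 CPM, prior count 2) were also planned, with 2000 transcripts and a prior count of 0.5 as alternatives.

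Other choices were made after seeing the data. Counts were summed per ID stem, libraries were thinned to the smallest total, and 2 control birds at the ends of components 2 and 3 were left out together. The bird's score on the first component of all 13742 transcripts, each scaled to unit variance, was added to the model. That component was examined after component 1 and component 2 of the 500 transcripts had been related to the calls made by random splits of the birds, and after the birds in one such split had been seen. Because its score is computed from the same counts that are then tested, adjusted p-values from that model can be too small, and it replaces no main result. The surrogate variables, though planned, are also computed from the tested counts, so the same limit holds for their adjusted p-values. Correlated transcripts were grouped without use of the labels, from 2000 transcripts by average linkage at a height of 0.5 and at least 20 members. That height was settled on after several others had been viewed with the group means in sight. The 8-fold criterion for transcripts high in 1 bird, component 3, the tests on sets, the full family of 14 component tests and the splits fitted with DESeq2 were also chosen after seeing the data.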

Results

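Ovarian RNA was sequenced from 20 female tree swallows (Tachycineta bicolor), a songbird that nests in cavities and competes for them. Nest boxes were taken away for a time to raise competition between wild birds, and ovaries came from 6 such birds at the peak of competition (Day 0) and from 4 birds 2 days later (Day 2). Date-matched birds that were left alone served as controls, with 5 on Day 0 and 5 on Day 2. Total counts ran from 5818117 to 15718893 per bird. They averaged 11288674 ± 2264711 (SD, n = 5) in Day 0 controls and 11132833 ± 1985055 (SD, n = 5) in Day 2 controls. Experimental birds averaged 8560733 ± 2531933 (SD, n = 6) on Day 0 and 10865253 ± 3356770 (SD, n = 4) on Day 2. The lower depth of the Day 0 experimental birds against their controls did not pass an exact permutation test (p = 0.0974, adjusted over 5 comparisons 0.487). The files pair the transcripts with no gene names, so the steroid synthesis genes and other genes of interest could not be looked up, and transcripts appear by ID.

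The 4 groups held a median of 15.7% of a transcript's variance. Random grouping gives a mean of 15.8%. A median and a mean are unlike measures, so these values do not show whether the groups held more than chance. Component 1 of the 500 most variable transcripts held 44.8% of their variance, component 2 held 13.6% and component 3 held 6.20%. Among 14 permutation tests of treatment and day on the first 2 components, the smallest p was 0.0507, for component 2 by day, and its adjusted value was 0.472. The first component of all 13742 transcripts, examined after the other results were seen, held 27.5% of variance, and the 4 groups held 9.49% of the variance of its scores (4.80% without experimental bird 3 of Day 0 to 18.6% without control bird 2 of Day 2). Experimental birds 1 and 3 of Day 0, control bird 5 of Day 0 and control bird 2 of Day 2 had the highest scores.

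**Figure D1:**
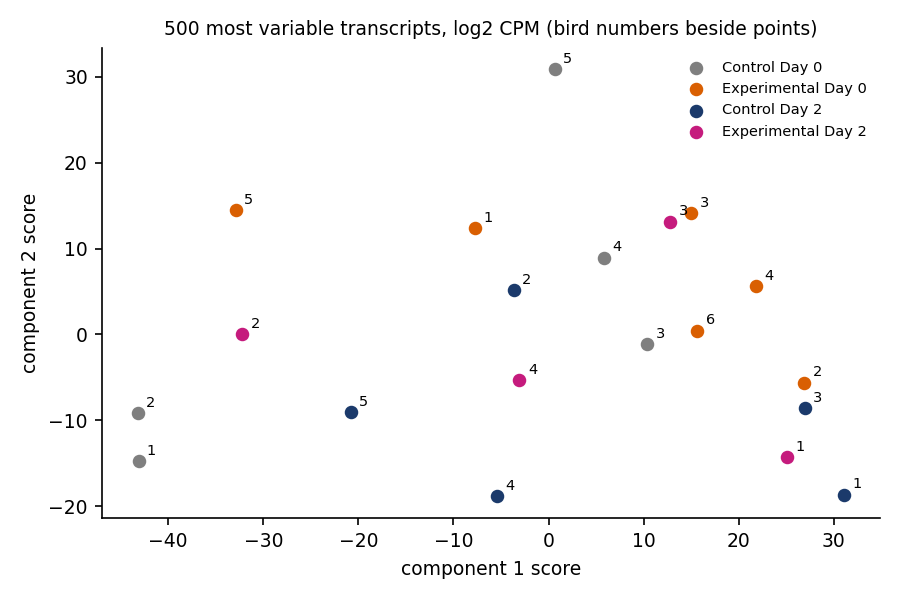
Scores of the 20 birds on component 1 (x axis) and component 2 (y axis) of the 500 most variable transcripts, coloured by group with bird numbers beside the points. Control birds 1 and 2 of Day 0 lie at the left end of component 1, with scores of -43.1 and -43.2. Each group spreads widely along component 1. On component 2, Day 2 controls run from -18.9 to 5.19 and Day 0 experimental birds from -5.61 to 14.5.

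The first comparison asks whether competition altered ovarian expression at its peak. No transcript passed on Day 0 with edgeR. The transcript tree_swallow013392t1_sg0.0 averaged 118 CPM ± 22.9 (SD, n = 6) in experimental birds and 75.6 CPM ± 9.49 (SD, n = 5) in controls. The transcript tree_swallow009765t1_sg0.0 averaged 62.2 CPM ± 14.7 (SD, n = 6) against 33.6 CPM ± 6.01 (SD, n = 5). In the other direction, tree_swallow005002t1_sg0.0 averaged 1.72 CPM ± 0.835 (SD, n = 6) in experimental birds and 6.83 CPM ± 3.78 (SD, n = 5) in controls. The transcript tree_swallow005809t1_sg0.0 averaged 82.1 CPM ± 16.1 (SD, n = 6) against 169 CPM ± 52.1 (SD, n = 5). These had the smallest p in each direction, and their edgeR adjusted p was 0.447 in each case. With DESeq2 all 4 passed, at adjusted p from 0.0204 to 0.0295. By edgeR's quasi-likelihood test 0 of 13742 transcripts were called, with 1047 at an unadjusted p under 0.05 (568 higher and 479 lower). DESeq2 called 14, limma-voom 0 and edgeR with surrogate variables 0. The 95% interval of the log2 fold change lay within ±1 for 78.0% of transcripts, and 57.6% of simulated 2-fold changes and 87.8% of 4-fold changes were recovered. In that simulation 12.6 to 19.6 unaltered transcripts were called on average against 0 in the real fit, so these shares overstate what the real fit could detect.

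The second comparison asks what was present 2 days later. One transcript, tree_swallow001694t1_sg0.0, rose in experimental birds on Day 2. It averaged 74.8 CPM ± 27.0 (SD, n = 4), against 31.5 CPM ± 2.54 (SD, n = 5) in Day 2 controls, a log2 fold change of 1.25 (SE 0.195, edgeR adjusted p = 0.0361). The lowest experimental bird, at 50.7 CPM, lay above the highest control, at 34.0 CPM. This transcript was picked by the smallest p in these same counts, so that separation adds no support to the call. On Day 0 the same transcript averaged 34.7 CPM ± 4.69 (SD, n = 6) in experimental birds and 39.5 CPM ± 6.70 (SD, n = 5) in controls. The difference of its treatment effect between the days did not pass in the edgeR fit without covariates (log2 difference 1.44, SE 0.264, edgeR adjusted p = 0.174). It passed with the first component of all transcripts in the model (edgeR adjusted p = 0.0411), an alternative chosen after the data were seen. The call passed in 14 of 32 alternatives. Among the 14, an adjusted p under 0.10 is the main fit itself. The sum per ID stem leaves this transcript's own counts unchanged, since it is the only 1 with its stem. With 1 bird left out it passed in 5 of 20 cases, those without control birds 1, 4 or 5 of Day 0 or experimental birds 2 or 4 of Day 2, over adjusted p from 0.00841 to 0.187. The log2 fold change stayed between 1.04 and 1.39 in all 32 alternatives.

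**Figure D2:**
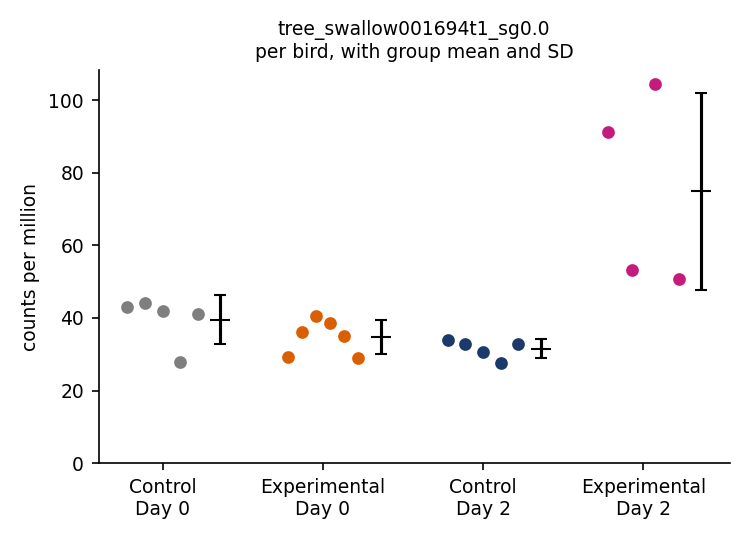
CPM of tree_swallow001694t1_sg0.0 (y axis) in each bird by group (x axis), with points for birds and bars for the group mean and SD. The 4 experimental birds of Day 2 lie between 50.7 and 104 CPM, above the 5 controls of that day, which lie between 27.6 and 34.0 CPM. The transcript was picked by its small p in these counts.

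Other transcripts of small p on Day 2 did not pass in the edgeR fit of all 20 birds without covariates. The transcript tree_swallow011931t1_sg0.0 averaged 41.0 CPM ± 10.8 (SD, n = 4) in experimental birds and 19.5 CPM ± 5.10 (SD, n = 5) in controls (edgeR adjusted p = 0.125). The transcript tree_swallow009929t1_sg0.0 averaged 43.0 CPM ± 14.8 (SD, n = 4) against 242 CPM ± 65.6 (SD, n = 5), with an edgeR adjusted p of 0.122. The transcript tree_swallow005543t1_sg0.0 averaged 89.6 CPM ± 16.1 (SD, n = 4) against 143 CPM ± 20.5 (SD, n = 5), with an edgeR adjusted p of 0.209. On Day 0 it averaged 93.7 CPM ± 13.3 (SD, n = 6) in experimental birds and 83.0 CPM ± 7.71 (SD, n = 5) in controls. The Day 2 controls were thus the group that stood apart. With only the compared groups in the edgeR fit, tree_swallow009929t1_sg0.0 was the 1 call (adjusted p = 0.0158) and tree_swallow001694t1_sg0.0 was not called (adjusted p = 0.286). The former also passed in edgeR without control bird 1 or 5 of Day 0 (adjusted p = 0.0306 and 0.0360). With surrogate variables in edgeR, tree_swallow011931t1_sg0.0 and tree_swallow005543t1_sg0.0 passed (adjusted p = 0.0341 and 0.0282). All 3 passed with DESeq2 and with limma-voom. In total 1 transcript was called by edgeR and 836 had an unadjusted p under 0.05 (489 higher and 347 lower). That unadjusted count was 1934 with limma-voom and 1493 with surrogate variables. DESeq2 called 17 transcripts (15 higher), limma-voom 14 (12 higher) and edgeR with surrogate variables 8 (7 higher). With the added component in the model 8 were called. Without control bird 1 of Day 2 the 1 call was tree_swallow000273t1_sg0.0, named after its values were seen (log2 fold change 1.47, edgeR adjusted p = 0.00588, against 0.168 with all birds). It also passed with DESeq2, limma-voom, surrogate variables and the added component. Of the 17, 13 were also among those of limma-voom and 6 among those found with surrogate variables. In simulation 47.5% of 2-fold and 84.7% of 4-fold changes were recovered.

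Averaged over both days, treatment gave 0 calls with edgeR, with 412 transcripts at an unadjusted p under 0.05, and 0 with DESeq2, limma-voom or surrogate variables. The interaction, which tests whether the treatment effect differed between the days, gave 0 calls with edgeR, with 1560 at an unadjusted p under 0.05 and a smallest adjusted p of 0.174. DESeq2 called 84 for the interaction, and limma-voom and surrogate variables called 0, and the model with the added component called 13. Across 13742 transcripts, the log2 fold changes of the 2 days had Pearson's r of -0.187 and Spearman's rho of -0.265, where transcripts are not independent replicates. Without experimental bird 2 of Day 2, r was 0.0144. At an unadjusted p under 0.05, 4 transcripts were higher on both days where independent lists give 20.2, and 4 were lower on both where they give 12.1.

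Control birds of the 2 days served as the background for these comparisons. The transcript tree_swallow005543t1_sg0.0 averaged 143 CPM ± 20.5 (SD, n = 5) in Day 2 controls and 83.0 CPM ± 7.71 (SD, n = 5) in Day 0 controls. The same Day 2 control libraries gave its lower value under treatment on Day 2, so the 2 results are not independent. The transcript tree_swallow001676t1_sg0.0 averaged 277 CPM ± 41.1 (SD, n = 5) against 153 CPM ± 16.8 (SD, n = 5). The transcript tree_swallow000226t2_sg0.1 averaged 28.1 CPM ± 4.93 (SD, n = 5) against 48.6 CPM ± 7.02 (SD, n = 5). The transcript tree_swallow050446t1_sg0.0 averaged 0.146 CPM ± 0.163 (SD, n = 5) against 4.43 CPM ± 5.90 (SD, n = 5), where Day 0 birds ranged from 0.285 to 14.6 CPM. None passed in the edgeR fit without covariates, which called 0 transcripts, with 1880 at an unadjusted p under 0.05 (754 higher and 1126 lower on Day 2), 18 at an adjusted p under 0.10 and a smallest adjusted p of 0.0951. DESeq2 called 184, surrogate variables 3, limma-voom 0 and the model with the added component 29. All 4 named transcripts were among the calls of DESeq2 and of the model with the added component (adjusted p = 0.00368 for tree_swallow005543t1_sg0.0 and 0.0368 for the others). With edgeR, tree_swallow005543t1_sg0.0 also passed with surrogate variables (adjusted p = 0.0251), without control bird 2 of Day 2 (0.0499) and without experimental bird 1 of Day 2 (0.0493).

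Between the days in experimental birds, edgeR called 0 transcripts, with 701 at an unadjusted p under 0.05 (320 higher and 381 lower on Day 2). The smallest adjusted p, 0.0929, was that of tree_swallow001694t1_sg0.0, with a log2 fold change of 1.11 (SE 0.188). That transcript passed with DESeq2 (adjusted p = 0.000278) and with edgeR without control bird 4 of Day 0 (0.0489) or experimental bird 2 or 4 of Day 2 (0.0304 and 0.0186). DESeq2 called 9 transcripts, limma-voom 1 and surrogate variables 0.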

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

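Every test in this part was chosen after its result was seen, apart from the rank correlations with component 1 of the 500 most variable transcripts.

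In 6 cases a value lay far from the other birds of its group, where 80 group tests give about 4 by chance. The component 3 score of control bird 5 of Day 2 was 34.3, against -4.51 to -1.62 in the other 4. Mean log2 CPM of set C, 23 transcripts that vary together, was 5.40 in that bird and -0.20 to 0.44 in the others. Mean log2 CPM of set A, 482 such transcripts, was 3.63 in control bird 5 of Day 0 and 2.10 to 2.47 in the others. The transcript tree_swallow001694t1_sg0.0 had 27.8 CPM in control bird 4 of Day 0 and 41.0 to 44.2 in the others. The transcript tree_swallow005543t1_sg0.0 had 69.3 CPM in control bird 5 of Day 0 and 85.9 to 87.7 in the others. The transcript tree_swallow000226t2_sg0.1 had 60.6 CPM in control bird 4 of Day 0 and 42.1 to 47.4 in the others.

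Among 100 splits of the Day 0 birds into groups of the study's sizes, one other split gave 1222 edgeR calls, and one split of the experimental birds gave 789, where the real groupings gave 0, which points to a structure of the samples. Separation along component 1 of the 500 transcripts, tried first, related weakly to the counts at unadjusted p (rho 0.289 for Day 0 and 0.0715 for experimental birds), and component 2, tried next, gave 0.396 and 0.181. The first component of all tested transcripts, tried last, holds 27.5% of variance and gave 0.752 and 0.837, which decides nothing about a cause, because a split along the main direction of the tested transcripts raises their count of small p by construction. On Day 2 components 1 and 2 and the axis gave 0.143, 0.399 and 0.385, and in controls 0.374, 0.348 and 0.614. Scores on the first component of all tested transcripts had an r of 0.122 with the share of the 10 most abundant transcripts (95% interval -0.339 to 0.536). The 4 groups held 9.49% of the variance of these scores (4.80% to 18.6% with 1 bird left out). Library depth stays open (r -0.374, with a 95% interval that reached the bound set), although scores at equal depth matched these scores (r 0.9999).

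Set B, 281 transcripts that vary together, differed 14.0-fold in geometric mean CPM between the lowest and the highest bird, and its share of reads ran from 0.0630% to 1.95%. The level followed neither depth (r 0.233) nor the share of the 10 most abundant transcripts (r 0.0250), and the 4 groups held 11.9% of its variance (4.31% without control bird 1 of Day 0 to 19.8% without experimental bird 5 of Day 0). The level did follow the number of transcripts detected at equal depth (r 0.782, rho 0.824, permutation p adjusted over 12 relations 0.00024 and 0.00036). The members of the set are themselves among the transcripts counted as detected. Part of this relation can therefore be built in, and these p-values do not measure an independent link. Another cell type or organ in varying amounts may be the source, but 0 IDs matched a marker symbol, so this cannot be told apart from a difference within the ovary.

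Set C stood out in 1 bird, control bird 5 of Day 2, at 0.413% of its reads. Over the 20 birds its level did not follow depth (r -0.127). The share of the 10 most abundant transcripts stays open (r 0.431, rho 0.0316), since this bird had the highest such share of the 20, at 6.27%. Without the 2 birds farthest from the median share, this bird among them, r was -0.0141. Another cell type or organ in that sample could be the source, and with 0 IDs matched to a marker symbol this cannot be told apart from a state of that bird's ovary. No biological explanation was tested for sets B and C beyond the study's groups.

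Whether chance splits of the same birds give results as large was counted over 100 splits, the real one included. Where edgeR made 0 calls the count decides nothing, since all 100 splits give at least 0. The highest other count was 1222 on Day 0, 26 averaged, 115 for the interaction, 13 for days in controls and 789 for days in experimental birds. For the 1 call on Day 2, 7 splits gave as many, with up to 10, so chance is not excluded. At unadjusted p, as many were given by 26 splits on Day 0 (real 1047, highest other 4123), 25 on Day 2 (836, 1795), 77 averaged (412, 2820), 7 for the interaction (1560, 3316) and 35 for days in experimental birds (701, 3886). For days in controls it was 4 (1880, 2659), under 5% of the splits. With DESeq2, 19 splits gave as many on Day 0 (14, 2003), 15 on Day 2 (17, 257) and 3 for days in controls (184, 223). DESeq2 also made at least 1 call in 52, 67 and 61 of the 99 other splits of those comparisons. No splits were fitted with limma-voom or with surrogate variables, so their calls have no such background. The shares of 4 and 3 splits belong to 1 comparison and are not adjusted for the 16 split counts made. The negative correlation between the days was matched or exceeded by 14 of 100 relabellings (real -0.187, lowest other -0.522).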

How the results depend on the processing

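Stem sums, thinning, leaving out both extreme control birds and the added component were chosen after the results were seen. The alternatives gave at least 1 call in 1 of 32 on Day 0, 16 of 32 on Day 2 and 0 of 31 averaged. It was 3 of 31 for the interaction, 6 of 32 in controls and 6 of 32 in experimental birds, not always of the same transcript. An adjusted p under 0.10, counted among these, is the main fit at a looser threshold. In 376 pairs of a named transcript and an alternative, 326 kept their status, 18 lost a call and 32 gained one. All 18 losses were of tree_swallow001694t1_sg0.0, the only named transcript called in the main fit, over its 32 alternatives. The other named transcripts had no call to lose, so the 326 say little about stability. No pair reversed in direction, which was unlikely from the start, since the named transcripts were picked by small p in the same counts. DESeq2 gave 14 calls on Day 0, 17 on Day 2, 84 for the interaction, 184 between days in controls and 9 in experimental birds, against 0, 1, 0, 0 and 0. Limma-voom gave 14 on Day 2 and 1 between days in experimental birds. Surrogate variables gave 8 on Day 2 and 3 in controls. An adjusted p under 0.10 gave 18 in controls and 1 in experimental birds. With the first component of all transcripts in the model, calls were 8 on Day 2, 13 for the interaction and 29 in controls. Libraries thinned to the smallest total gave 0 on Day 2, as did leaving out both extreme control birds, while the log2 fold change of tree_swallow001694t1_sg0.0 was 1.21 and 1.26 there (adjusted p 0.0805 and 0.121), against 1.25. The cause was not tested. With 1 bird left out, counts ran from 0 to 0 on Day 0 and averaged, 0 to 2 on Day 2 (2 without control bird 1 or 5 of Day 0), 0 to 2 for the interaction (2 without control bird 1 of Day 2), 0 to 3 in controls (3 without experimental bird 1 of Day 2) and 0 to 1 in experimental birds. Unadjusted counts then ran from 768 to 1390, 515 to 1207, 331 to 607, 1139 to 1837, 1369 to 2046 and 459 to 905, in the order of treatment on Day 0, on Day 2, averaged, interaction, controls and experimental birds. The correlation between the days ran from -0.314 to 0.0144. Component 1 held 31.2% of variance with 2000 transcripts. List tests and sums per symbol were not run, since no ID matched a symbol. No paired analysis was possible because bird numbers pair no birds across groups. At these depths 47.5% to 57.6% of simulated 2-fold changes were recovered, depending on the comparison, under a threshold loosened by the simulated changes.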

Other observations

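The tests in this part were chosen after the data were seen.

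Transcripts that vary together were grouped without using treatment or day. Set A had 482 members and followed component 2 (r 0.884), set B had 281 and followed component 1 (r -0.990), set C had 23 and set D 20. The 4 groups held 27.5% of the variance of set A (18.9% to 40.6% with 1 bird left out). No difference in set level between groups passed in 20 exact permutation tests, where the smallest p was 0.0714 with an adjusted value of 0.794. For set C the size of p depends on control bird 5 of Day 2, a bird flagged for its set C level. Without it the groups held 60.2% of the variance of set C, against 3.96% with it. The other 4 Day 2 controls averaged a log2 CPM of 0.16 ± 0.29 (SD, n = 4) and Day 0 controls 1.12 ± 0.22 (SD, n = 5), with an exact permutation p of 0.00794, the smallest the design allows. That p was 0.0198 adjusted over the 5 tests without the bird and 0.0992 over these and the 20 tests together. The interaction had p = 0.0038 in the same permutation test (adjusted 0.0190 and 0.0951). At heights of 0.4 and 0.6 the same linkage gave sets that overlapped sets A and B. Such overlap is built in, because cuts of the same linkage are nested, so it does not show that the sets would recur in other birds. Sets C and D had no match of at least 20 members at 0.4. Set B took 1.95% and 1.71% of reads in control birds 1 and 2 of Day 0, 0.966% in experimental bird 5 of Day 0, 0.905% in experimental bird 2 of Day 2 and 0.614% in control bird 5 of Day 2. The other 15 birds had 0.0630% to 0.277%.

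The first component of all tested transcripts had its highest scores in experimental birds 3 and 1 of Day 0 (140 and 116), control bird 5 of Day 0 (88.5) and control bird 2 of Day 2 (65.1). The other 16 birds scored from -71.4 to 25.0. The score rose with the number of transcripts detected at equal depth (r 0.648, permutation p = 0.00196, adjusted 0.00784 over 12 relations, rho 0.733, permutation p = 0.0004, adjusted 0.0012). Without the 2 birds farthest from the median number detected, r was 0.638. The transcripts behind this score and the members of the sets are themselves among those counted as detected. Part of each such relation can therefore be built in, and these p-values do not measure an independent link. The relation was not particular to this score. Set A (r 0.795, rho 0.786) and set B (r 0.782, rho 0.824) also followed the number detected, with adjusted permutation p of 0.00024 for both r. For set C rho was 0.726 (adjusted permutation p = 0.0012) and r 0.372 (adjusted 0.210). In 5 exact permutation tests between groups the smallest adjusted p was 0.831.

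Control bird 5 of Day 2 had 13 transcripts more than 8-fold above every other bird, which summed to 3197 CPM. The other birds had at most 3.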
